A study of Homo sapiens with 22 samples.

How the data were processed

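THP-1, a human monocytic leukaemia line, carried a lentivirus with either a short hairpin against QKI5 or a control hairpin, per the sample labels. The series design text calls the control cells untreated, and the sample labels were followed here. The 22 samples form 10 groups. Each condition had 2 H3K4me3 ChIP, 2 Pol II ChIP, 2 QKI5 CLIP and 2 CLIP input samples, with 2 ChIP inputs for control and 4 for knockdown. Chromatin immunoprecipitation (ChIP) followed by sequencing maps the DNA bound by a protein or carrying a histone mark, and crosslinking immunoprecipitation (CLIP) maps the RNA that a protein touches.

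The authors deposited 6 peak lists, 1 per assay and condition, each made from both replicates per the series design text. The submitters' processing notes name HOMER and the build GRCh38.p5 without saying for which step or in which order they were used. The aligner, the peak caller, its settings and the use of the inputs are not given in the sources used here. Reads and per-replicate signal were not analysed here, so the depth of each sample is unknown and the spread between replicates could not be measured. No p-value is given for any difference between conditions.

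In the 4 ChIP lists deposited by the authors, the score is 1 and the strand is plus at every peak, so the score ranks nothing and peaks were ranked by their width. The narrowest peaks, 501 bp wide, are also the most common in each list. The CLIP lists have no header, and their units were read from the values. The authors' CLIP columns were taken as the -log10 p of each peak, from 7.00 in control and 7.04 in knockdown up to 400.0, and as its log2 enrichment, from 3.00 and 3.02. A read number, a gene identifier and a symbol accompany each CLIP peak. These peak values are the authors' and were used only to describe and rank peaks within their own list.

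The linear enrichment of a CLIP peak equalled its read number divided by a whole number, times 15.2 in the control list and 30.9 in the knockdown list. The divisor was whole within 0.001 for 98.9% of control and 95.1% of knockdown peaks. A one-sided binomial test of those reads gave the deposited -log10 p within 0.01 for 4406 of 4410 control and 296 of 296 knockdown peaks with at most 3 background reads and a -log10 p under 15. The factors have the form of a ratio of background to CLIP read totals, 2.03 times as large in knockdown as in control. That arithmetic was inferred from the values, and no source states it.

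Peaks on chromosomes 1 to 22, X and Y were compared. A peak counted as shared when a peak of the other list overlapped it by at least 1 bp, on the same strand for CLIP. The random level is the mean over 100 random sets. ChIP peaks were placed at random on their own chromosome. For CLIP peaks, windows were placed within the same genes, both for the overlap between conditions and for that with ChIP peaks. These windows cover only CLIP peaks with a matched gene, while the observed overlap between conditions covers all CLIP peaks. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and differences of shares carry Newcombe intervals. Intervals cover counting error only, since neighbouring peaks and reads are not independent and the cultures are not compared.

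The planned definition of a promoter peak needed transcript starts of the build used, and no such annotation was used here. It was replaced by a gene-end peak, which lies within 1 kb of either outer end of a gene. Gene names and neighbourhood came from a RefSeq table of GRCh38.p14, which gives no strand and none of whose coordinates are printed. The table held 20037 protein-coding genes, and 94.0% of control and 90.1% of knockdown CLIP peaks had an identifier that matched it. Where CLIP gave the strand of a gene, 99.2% of the genes with a control H3K4me3 gene-end peak and 96.8% of those with a Pol II peak had it at the 5' end. A promoter inside the outermost span of a gene is missed by this definition, and 33.6% of the genes with a Pol II peak also had one at the 3' end. Exons, introns and the ACUAAY element recognised by QKI were not analysed here, because they need an annotation and a genome sequence of the build used. A gene present in a single list has a gene-end peak there and none in the other list. The stricter 5 kb rule asks for no peak of the other list within 5 kb of either gene end, whatever the distance between the peaks themselves.

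Genes with a control CLIP peak, called CLIP genes, were compared with 10000 random gene lists of the same size drawn from the genes that could have changed. Random lists were matched in 5 classes of gene length for gains, and also in 5 classes of control peak width for losses. A count was said to stand apart when its percentile lay below 2.5 or above 97.5, which describes these lists and is not a test of the conditions. The 13 gene lists were fixed before the data were examined. They hold macrophage and monocyte genes, granule and progenitor genes, myeloid transcription factors, chemokines and cytokines, interferon response genes, immediate early genes, cell cycle genes, ribosomal protein genes, hnRNP and SR splicing factors, QKI RNA targets known from other cells, abundant non-coding RNA genes, chromatin regulators and genes of other cell types. Their CLIP members were compared with random lists of genes that have a control Pol II gene-end peak, matched on gene length, for the 12 lists with at least 5 such members.

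Named genes also followed a rule fixed beforehand. QKI comes first and CXCL2 next. For each ChIP mark and direction the 10 genes with the widest peak present in a single list follow, with up to 6 members of the fixed lists. For CLIP they are the 10 genes with the strongest control peak absent from knockdown, the 10 with the strongest knockdown peak, and up to 6 members of each fixed list with a control peak. Genes of a single list that share a peak were named together, and loci without a symbol were passed over. Some genes that the rule names are not reported here.

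Other settings chosen beforehand were an overlap of at least 50% of each peak, peaks within 500 bp, the stronger part of each list above its median, lists limited to the same length, all contigs, strand ignored, small and mitochondrial RNA left out, gene ends within 500 bp or 2 kb, all gene biotypes, absence only with no peak within 5 kb, other matching and other sets of CLIP genes. Stronger meant wider for ChIP peaks, whose score ranks nothing, and a higher -log10 p for CLIP peaks. Overlap functions tested on simulated data gave the known answer for 2000 of 2000 intervals, and the gene-end search for 500 of 500. For the comparison of new Pol II peaks at CLIP genes, 200 simulated lists of 464 among 8103 genes lay outside the bounds in 5.5% of runs with no effect, 86.5% with a 1.5-fold effect and 100% with a 2-fold effect. Members of the simulated lists were drawn without regard to gene length or expression. These rates therefore do not show how the percentile behaves for real CLIP genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.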

Results

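The data describe where H3K4me3, the histone mark of active promoters, and RNA polymerase II (Pol II) lay on DNA, and which RNA sites came down with QKI5, in THP-1 cells with and without QKI5 knockdown. QKI5 is the nuclear isoform of QKI, an RNA-binding protein known for its part in splicing. The series title asks about a role of QKI5 in transcription during monocytic differentiation. On chromosomes 1 to 22, X and Y the control and knockdown lists held 21953 and 21358 H3K4me3 peaks, 33370 and 35094 Pol II peaks, and 7300 and 649 QKI5 CLIP peaks. H3K4me3 peaks had median widths of 2572 and 2599 bp and covered 62.8 and 60.6 Mb, and Pol II peaks had median widths of 923 and 952 bp and covered 56.7 and 60.4 Mb. Each list pools both replicates, so no value below has a replicate check.

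QKI kept both marks at its gene end in knockdown. On chromosome 6 (GRCh38.p5), its H3K4me3 peak spanned 163410696 to 163420940 in control, 10245 bp, and 163411813 to 163419921 in knockdown, 8109 bp. The Pol II peak spanned 163411618 to 163418259 in control, 6642 bp, and 163411030 to 163417983 in knockdown, 6954 bp. QKI RNA itself carried 1 control CLIP peak, at 163448330 to 163448369 on the plus strand, with 9 reads, a log2 enrichment of 5.09 and a -log10 p of 8.13, and no knockdown peak. The lists hold no QKI5 RNA or protein level, so the knockdown itself could not be checked from them.

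**Figure D1:**
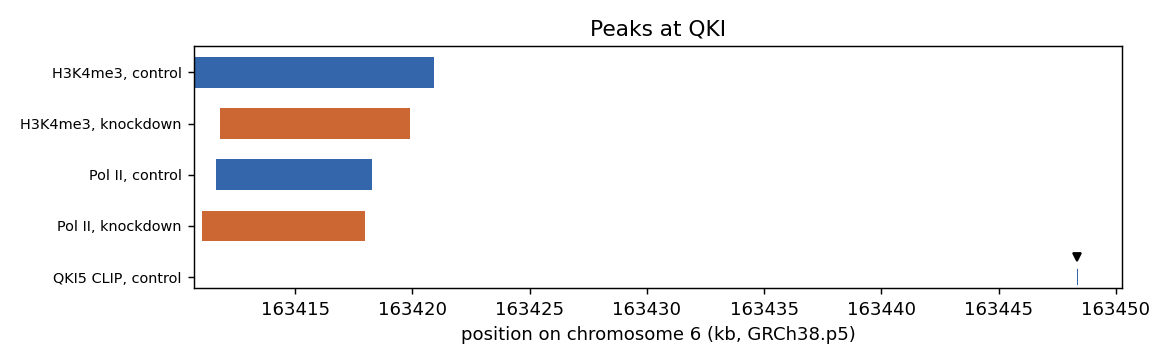
Peaks at QKI against position on chromosome 6 in kb, 1 row per list, with control in blue and knockdown in orange. The 4 ChIP peaks lie together at the start of the gene, and the arrowhead marks the single control CLIP peak, at 163448330.

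CXCL2, a chemokine that attracts neutrophils, also had both marks in both conditions. Its H3K4me3 peak on chromosome 4 ran from 74097857 to 74100035 in control, 2179 bp, and from 74097909 to 74100082 in knockdown, 2174 bp. Its Pol II peak ran from 74098655 to 74099957 in control, 1303 bp, and from 74098636 to 74099708 in knockdown, 1073 bp. No CLIP peak was listed at CXCL2 in either condition. Its neighbour in function CXCL3 had H3K4me3 peaks of 2427 bp in control and 3163 bp in knockdown and a Pol II peak in knockdown alone, 774 bp wide.

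The comparison of the H3K4me3 lists asks which promoters gained or lost the mark after knockdown. Nearly all protein-coding genes with a gene-end peak had one in both lists, 13350 genes, with 111 in control alone and 156 in knockdown alone. Among genes with no peak of the other list within 5 kb, the 10 widest control peaks were at SMOC1 (2011 bp), the mitochondrial ribosomal protein gene MRPL45 (1350 bp), the opioid receptor gene OPRM1 (1293 bp), CCL3, a macrophage inflammatory chemokine (1101 bp), PODN, MARCHF4, LILRB2, LILRB1, APOL3 and NCOA2 (815 bp). The CCL3 peak lay at 36089229 to 36090329 on chromosome 17, 92030 bp from the nearest knockdown peak, but CCL3 had a Pol II gene-end peak there in both lists, 2327 bp in control and 2638 bp in knockdown. The 10 widest knockdown peaks were at MYEOV (1986 bp), ELAVL3, a neuronal RNA-binding protein gene (1645 bp), the hexokinase gene HK3 (1590 bp), PPL (1331 bp), PCDHB8, PLCG2, AMER3, C3orf62, ELAPOR1 and SLC60A1 (1182 bp). Of the fixed lists, MBNL2, a splicing regulator, had a 929 bp peak in knockdown alone. Naming genes by the 5 kb distance was chosen after their values were seen, except for CCL3 and MBNL2, which the rule for fixed lists names.

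The widest control peaks at genes without a knockdown gene-end peak were at VSIG4, a complement receptor of macrophages (8335 bp, chromosome X, 66012599 to 66020933), LY6G5B (6657 bp), RDH5, a retinol dehydrogenase (5700 bp), GLOD4, UBE2R2, IFT46, PKHD1L1, the nuclear receptor gene NR5A1, the parathyroid hormone-related gene PTHLH, and DIABLO, a mitochondrial activator of apoptosis (3800 bp). In knockdown they were at MSMP (6474 bp, chromosome 9, 35745661 to 35752134), RUSC1 (5707 bp), the NEDD8 protease gene SENP8 (5608 bp), DCAF1, TMED6, CIROP, PLEKHM2, DCDC2B, METTL9 and ARLN (4210 bp). At 10 of these 10 control genes and 10 of these 10 knockdown genes the peak overlapped a peak of the other list whose edge stopped more than 1 kb from the gene end. With absence defined by no peak within 5 kb, none of these 20 wide peaks counted, and the genes in a single list numbered 44 for control and 84 for knockdown. IFI44, an interferon-induced gene, had a 501 bp peak in control alone, 157354 bp from the nearest knockdown peak.

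By peaks, 19314 control H3K4me3 peaks, 88.0% (95% interval 87.5 to 88.4), overlapped a knockdown peak, and 19388 knockdown peaks, 90.8% (90.4 to 91.2), overlapped a control peak. Random placement gave 4.64% and 4.75%. Peaks shared by both lists had median widths of 2919 bp in control and 2833 bp in knockdown, while peaks of a single list had a median of 501 bp in both. Of the 501 bp peaks 31.6% in control and 42.9% in knockdown were shared, against 99.8% and 99.9% of those over 2000 and up to 4000 bp.

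The Pol II lists ask at which genes polymerase was found in a single condition. Gene-end peaks were in both lists at 11551 genes, in control alone at 383 and in knockdown alone at 795. Fixed-list members in knockdown alone were DNMT3A, which encodes a DNA methyltransferase (1496 bp, chromosome 2, 25340650 to 25342145, 19661 bp from the nearest control peak), ALAS2 of erythroid haem synthesis (1463 bp), ATF3, a stress-induced transcription factor (1414 bp), the interferon-induced OAS3 (895 bp) and OASL (815 bp), and CXCL3. Smaller peaks in knockdown alone were at LIF (669 bp), CEBPE (665 bp), CXCL16 (626 bp), ISG20 (501 bp) and CSF1R (755 bp), named after their values were seen. ALAS2, CEBPE, ISG20 and CSF1R had no H3K4me3 gene-end peak in either list. By the minus strand of its CLIP peak, the ALAS2 Pol II peak lay at the 3' end of the gene, so it is not a promoter peak. A gene-end peak can lie at either end, and which end it was is not given for the other genes named here. In control alone the fixed-list members included the B-cell gene CD79A (2977 bp) and the myeloid receptor genes FCGR3A (1201 bp) and ITGAM (772 bp). At CD79A, FCGR3A and ATF3 the peak overlapped a peak of the other list, at ITGAM the nearest lay 2687 bp away, and these genes and OAS3 did not count as present in a single list under the 5 kb rule. CSF1R was not among the genes kept by that rule either, although its peak is wider than those of LIF and CEBPE, which were kept.

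Among the widest Pol II peaks in control alone were those at MATN2, a matrix protein gene (10841 bp), BGLAP and PAQR6, which share a peak (7751 bp, chromosome 1, 156240987 to 156248737), PDE6G, the histone gene H4C7, MYH14, RGS20, the proteasome gene PSMA6, and GARIN5B (4426 bp). The MATN2 peak is also the control peak of the ribosomal protein gene RPL30. RPL30 had a Pol II gene-end peak in both lists, 7402 bp wide in knockdown, so this peak is not particular to MATN2 or to control. In knockdown alone they were at LINGO3 (13426 bp, chromosome 19, 2295269 to 2308694), PSTPIP1, a cytoskeletal adaptor of blood cells (9067 bp), DQX1 (8497 bp), the ion channel gene HCN2 (8019 bp), RNF207, CIMAP1C, GGT1, BLOC1S3 and TRAPPC6A, which share a peak (4991 bp, 14959 bp from the nearest control peak), CAMK4, and the lipoxygenase gene ALOX12 (4408 bp). Of the genes with the widest peaks, the peak overlapped one of the other list at 9 of 11 in control and 8 of 11 in knockdown. With absence defined by no peak within 5 kb, 168 genes were left in control alone and 496 in knockdown alone. By a naming chosen after their values were seen, the widest of these in control were at BGLAP, COL20A1 (4041 bp), DDT and DDTL, which share a peak (3301 bp), C12orf76 (2614 bp) and G0S2, an inhibitor of lipolysis (2578 bp). The BGLAP peak lay 1853 bp from a knockdown peak, which the rule does not count because it measures from the gene ends. In knockdown they were at BLOC1S3, the aminopeptidase gene NPEPPS (3810 bp), BBX (3536 bp), SORT1, a sorting receptor gene (3492 bp), and ZNRF1 (3016 bp).

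By peaks, 21116 control Pol II peaks, 63.3% (62.8 to 63.8), overlapped a knockdown peak and 20852 knockdown peaks, 59.4% (58.9 to 59.9), overlapped a control peak, against 4.76% and 4.49% at random. Shared Pol II peaks had median widths of 1560 and 1696 bp, and peaks of a single list had a median of 501 bp in each. When at least 50% of each peak had to overlap, 43.4% of control and 41.3% of knockdown peaks were shared. Of the 501 bp peaks 25.5% and 21.3% were shared, and of those over 4000 bp 99.2% and 98.9%.

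**Figure D2:**
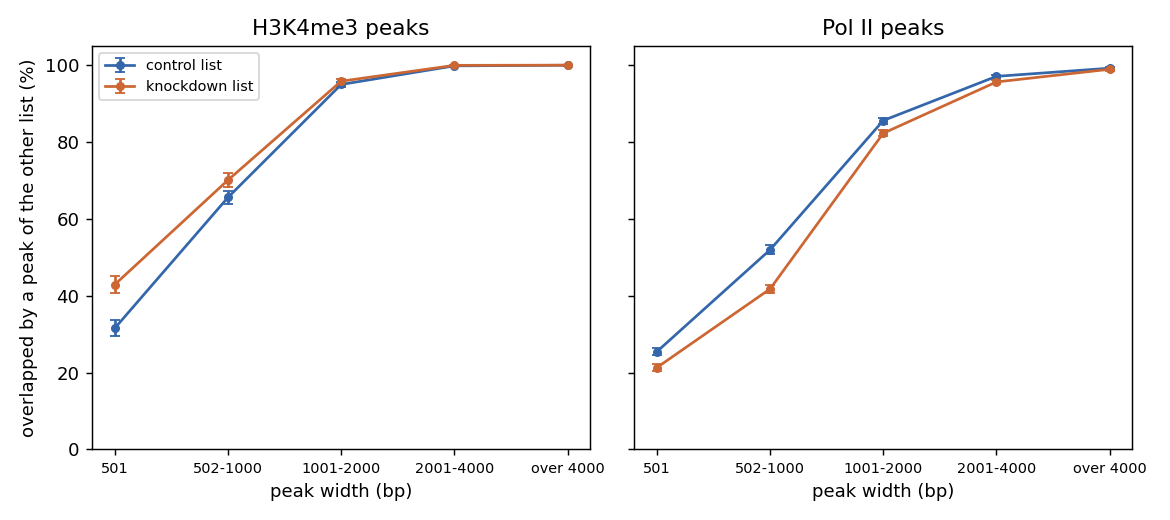
Share of peaks overlapped by a peak of the other condition's list, in percent, by peak width in bp, for H3K4me3 (left) and Pol II (right), with control in blue, knockdown in orange and exact 95% binomial intervals as bars. The share rises from 31.6% and 42.9% (H3K4me3) and 25.5% and 21.3% (Pol II) at 501 bp to 98.9% or more above 4000 bp.

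The marks were then set beside each other. H3K4me3 peaks lay on a Pol II peak for 65.6% of the control list and 69.6% of the knockdown list. Shared Pol II peaks lay on an H3K4me3 peak in 66.5% of control and 65.6% of knockdown cases, and Pol II peaks of a single list in 14.5% and 17.0%. Both marks were in knockdown alone at 21 genes, where independent marks would give 6.19. These were MAD2L2, SYCP1, CRABP2, NLRC4, PLCD1, BDH1, S100P, HK3, NHLRC1, AIF1, NOS3, PKP3, MCAM, SDS, PPP1R36, PRSS36, CD79B, C3, ZNF99, RASL10A and 1 locus without a symbol. Both were in control alone at 5 genes, PCDHGB5, TXLNB, NCOA2, ART1 and CD248, where independence would give 2.12. H3K4me3 was in control alone and Pol II in knockdown alone at 9 genes, against 4.40, namely HGD, TLR1, HLA-C, CALHM3, CD300LB, CYGB, CCL25, EML2 and 1 locus without a symbol. The opposite held at 5 genes, RTN4, MYEOV, CFAP97D2, CIROP and PTPRH, against 2.98. The independent level was taken over all protein-coding genes, including those that could not change in the direction counted, so it is not a matched baseline. All 4 sets lay above it, also those of opposite direction, so the excess does not show that the marks changed together. The genes of these 4 sets were named after their values were seen, and neither these counts nor any theme among the genes was tested.

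Across the fixed lists, gene-end peaks were mostly in both conditions. All 35 ribosomal protein genes had both marks in both lists. With each mark counted alone, peaks were in both lists at 27 of 28 cell cycle genes, 44 of 46 splicing factor genes, 28 of 30 chromatin regulators and 20 of 21 myeloid transcription factors. The genes left out were not always the same for each mark. Of the cell cycle genes, CDKN1A had no H3K4me3 peak and CCND2 no Pol II peak. Of 24 macrophage and monocyte genes, 11 had H3K4me3 and 9 had Pol II in both, and of 11 granule and progenitor genes 8 had H3K4me3 and 8 had Pol II. Of 24 chemokines and cytokines, 15 had H3K4me3 and 10 had Pol II in both, with CXCL3, CXCL16 and LIF having Pol II in knockdown alone. Of 23 interferon response genes, 20 had H3K4me3 and 16 had Pol II in both, with ISG20, OAS3 and OASL having Pol II in knockdown alone. Immediate early genes had H3K4me3 in both for 18 of 18 and Pol II for 17 of 18, the exception being ATF3. Of 20 known QKI targets 15 and 16 had H3K4me3 and Pol II in both, and of 35 genes of other cell types 11 and 7 did.

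QKI5 CLIP asks which RNA sites came down with QKI5, and the knockdown list was made with the same antibody. Whether QKI5 contacts remain in the knockdown list was not tested. The strongest control peaks absent from knockdown included RPSA, a ribosomal protein gene (249 reads, log2 enrichment 3.09, chromosome 3, 39411054 to 39411105), and the long non-coding RNA DANCR (142 reads, 3.75). Others were at the U6 RNA loci RNU6-9 (105 reads, 10.06) and RNU6-5P (22 reads, 8.18), the heat-shock gene HSPA1B (104 reads, 3.08) and LINC00854 (99 reads, 3.91). The rest were at STAT5B, a transcription factor of cytokine signalling (48 reads, 3.65), H2AFX, now H2AX (57 reads, 3.08), and the cytoskeletal genes PLEC (39 reads, 3.82) and AHNAK (39 reads, 3.59). AHNAK carried 53 control peaks, CBFA2T3, a transcriptional corepressor gene, 37 and PLEC 30, with none in knockdown. With adjoining peaks merged these make 37, 24 and 23 sites, and the counts that follow are also of unmerged peaks. TRAPPC9 with 26, C7orf50 with 24, LINC01606 with 22 and HDAC4 with 17 control peaks had none in knockdown either. C22orf34 had 30 control and 7 knockdown peaks, ANKRD11 23 and 2, SMYD3 21 and 2, and MFGE8 19 and 4, and whether these lie at the same sites was not tested. The genes with many peaks were named after their values were seen, except AHNAK and PLEC. The strongest knockdown peaks were at LUC7L2, a splicing factor gene (239 reads, 5.48), the mitochondrial ribosomal RNA MT-RNR2 (236 reads, 3.89), SOX2-OT (195 reads, 4.56), NEAT1, the paraspeckle RNA (150 reads, 4.61), TMEM107 (139 reads, 3.07), KCTD2 (116 reads, 4.96), SNORD12B (67 reads, 4.38), the mitochondrial transfer RNAs MT-TT (8 reads, 8.06) and MT-TP (6 reads, 6.75), and RPSA at another site (50 reads, 3.48). No knockdown peak had fewer reads than MT-TP. Both transfer RNAs rank among the strongest only by a listed -log10 p at the highest value in the list. In the same way, the control peak at RNU6-5P, with 22 reads, outranks those of STAT5B (48 reads) and H2AFX (57 reads). The recalculation from reads did not cover that range of -log10 p. RPSA, DANCR and TMEM107 overlap or host small RNA genes, so the gene behind such a peak is uncertain.

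Over all contigs the lists held 7337 control and 669 knockdown peaks, 10.97 control peaks for each knockdown peak, or 9.58 with adjoining peaks merged. Of control peaks 132, 1.81% (1.52 to 2.14), overlapped a knockdown peak on the same strand, and 123 knockdown peaks, 19.0% (16.0 to 22.2), overlapped a control peak, against 0.191% and 1.38% at random. With both lists limited to the length of the shorter, 16.9% of control peaks overlapped a knockdown peak. Of the 368 protein-coding genes with a knockdown peak, 192 also had a control peak, 52.2%, where independent lists would give 13.9%. Median reads per peak were 9 in control and 8 in knockdown, and median log2 enrichments were 5.92 and 5.95. By the inferred arithmetic, 2743 of the 7254 control and 146 of the 636 knockdown peaks with a whole divisor had a divisor of 1. The enrichment of such a peak follows from its read number alone. Protein-coding genes took 83.3% of control and 74.3% of knockdown peaks, and long non-coding RNA genes 8.12% and 10.8%. Fewer listed peaks in knockdown do not by themselves give fewer contacts, since the depth of these libraries is unknown.

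Control CLIP peaks lay on H3K4me3 and Pol II peaks more often than windows placed in the same genes. On H3K4me3 peaks lay 13.0% (12.2 to 13.8), against 9.26% at random, and on Pol II peaks 13.2% (12.4 to 14.05), against 9.68%. Knockdown CLIP peaks gave 17.6% (14.6 to 20.9) against 14.5%, and 18.9% (15.9 to 22.3) against 17.2%. In the first 1 kb of protein-coding genes lay 313 of 5836 control peaks, 5.36% (4.80 to 5.97), against 2.83% at random, and 15 of 482 knockdown peaks, 3.11% (1.75 to 5.08), against 3.30%. In the last 1 kb lay 3.46% (3.01 to 3.96) of control peaks, against 2.86% at random, and 5.39% (3.55 to 7.80) of knockdown peaks, against 3.31%. CLIP genes carried the marks more often than other genes, 88.4% against 63.7% for H3K4me3 and 83.4% against 55.7% for Pol II. Genes with a knockdown CLIP peak did so as well, 88.9% against 67.0% and 87.2% against 61.1%. These contrasts were not matched on expression, and a gene needs RNA to yield a CLIP peak, so they do not set QKI5 contact apart from expression.

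Among the fixed lists, immediate early genes, which respond first to stimulation, stood apart for CLIP. JUN (43 reads, log2 enrichment 3.03), JUNB (36 reads, 3.01), MYC (15 reads, 5.02), ZFP36 (14 reads, 4.73), IER2 (14 reads, 4.27) and FOSB (8 reads, 6.92) carried control peaks and no knockdown peak, 6 of 17 where random lists averaged 1.26, at percentile 99.96. Without matching on gene length the percentile was 93.35, inside the bounds. The random lists for the fixed lists were not matched on expression, so this excess does not set QKI5 contact apart from expression. The enrichments of JUN and JUNB lie near the lowest of the control list. Of the 2794 protein-coding genes with a control CLIP peak, 192 also had a knockdown peak. The lack of a knockdown peak is therefore not particular to immediate early genes. Chromatin regulators reached percentile 97.51, just past the bound, with 13 of 28 against a random mean of 8.14, among them the acetyltransferase gene CREBBP (13 reads, 7.62), SETD2, ASXL1, KMT2D (14 reads, 4.03) and KMT2C. Known QKI targets had 6 of 16 at percentile 87.5, namely QKI itself, CD46, NUMB, FOXO1, ERBIN (listed as ERBB2IP) and UTRN.

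The other 9 lists tested lay within the bounds. Myeloid transcription factors had 5 of 20 at percentile 86.8, with SPI1, a key transcription factor of myeloid cells (14 reads, 5.41), RUNX1 (14 reads, 4.41), CEBPA, KLF4 and STAT3. Chemokines and cytokines had 2 of 10 at 81.2 (TGFB1 and VEGFA), ribosomal protein genes 3 of 35 at 63.5 (RPSA, RPS9 and RPL13A) and splicing factors 8 of 44 at 59.8, among them CELF2, HNRNPU, HNRNPH1, RBFOX2 and HNRNPM. Interferon response genes had 2 of 16 at 40.9, RIGI among them, and cell cycle genes 3 of 27 at 27.1, with the kinase gene CDK6 the strongest (77 reads, 4.55), then RB1 and CCND3. Of the genes just named, RUNX1, RPSA, RPL13A, CELF2, RBFOX2 and CDK6 also had 1 knockdown CLIP peak each, so these genes were not free of CLIP peaks in knockdown. Granule and progenitor genes had 0 of 8 at 10.6, macrophage and monocyte genes 0 of 11 at 10.5 and genes of other cell types 0 of 9 at 8.03. MPO, which encodes the granule enzyme myeloperoxidase (58 reads, 8.78), the cytoskeletal gene MACF1 (18 reads, 4.92), MSR1, S100A8, CCND2, MBNL2 and ALAS2 carried control CLIP peaks but had no control Pol II gene-end peak, which kept them out of these counts. Abundant non-coding RNA genes were not tested, with NEAT1 and KCNQ1OT1 in the control list and NEAT1 and GAS5 in the knockdown list.

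**Figure D3:**
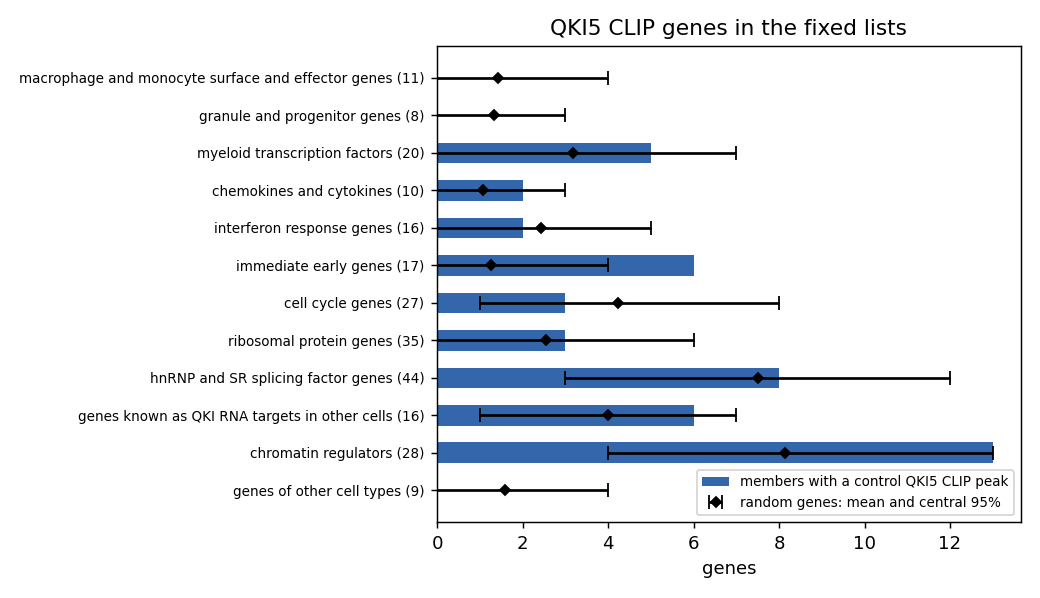
Number of members with a control QKI5 CLIP peak (blue bars) for the 12 gene lists tested, with the members tested in parentheses, and the mean and central 95% of 10000 random lists matched on gene length (black). Immediate early genes, at 6, lie past the random range, and chromatin regulators, at 13, lie on its upper bound.

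The last comparison asks whether CLIP genes lost or gained gene-end peaks after knockdown. New Pol II peaks at CLIP genes stood apart, at 100 of 464 genes, 21.6% (17.9 to 25.6), where matched random lists averaged 52.6, at percentile 100. Among them were NPEPPS, BBX, SORT1, MEF2B and DAPK1, which had no control peak within 5 kb. ALAS2 of the fixed lists, whose peak lay at its 3' end, was also among them. The end is not given for the other genes, nor for the 100 genes as a set. The count is therefore of gene-end peaks and not of promoter peaks. Control-only Pol II peaks, counted over CLIP genes without a knockdown peak, also stood apart, at 50 of 414 genes against a random mean of 24.6, at percentile 100. With no knockdown peak within 5 kb this count was 18 against 13.1, at percentile 92.3, inside the bounds. Genes with a knockdown CLIP peak gained Pol II peaks at 19 of 64, also at percentile 100, and the genes of both CLIP lists overlap. No random list was matched on expression, which the peak lists do not hold, while a CLIP gene must make RNA. These counts therefore do not tie the excess of new Pol II peaks to QKI5 contact. Lost Pol II peaks were 50 of 2330, against 57.8, at percentile 11.1, and 18 of 2330 with no knockdown peak within 5 kb, at percentile 1.42, outside the bounds. With matching also on H3K4me3 peak width the percentile of the 50 was 27.9. For H3K4me3, 6 of 2471 CLIP genes lost the peak, against 12.8, at percentile 1.42, and 15 of 323 gained it, against 8.97, at percentile 97.8. Both H3K4me3 percentiles moved inside the bounds under several alternatives, to 8.76 and 30.8 with CLIP genes of the stronger peaks. Over CLIP genes without a knockdown H3K4me3 peak, 6 of 314 had one in control alone, at percentile 40.2. The counts over genes without a knockdown peak and over knockdown CLIP genes, the 5 kb rule at CLIP genes and the matching on H3K4me3 width were chosen after the gain had been seen.

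**Figure D4:**
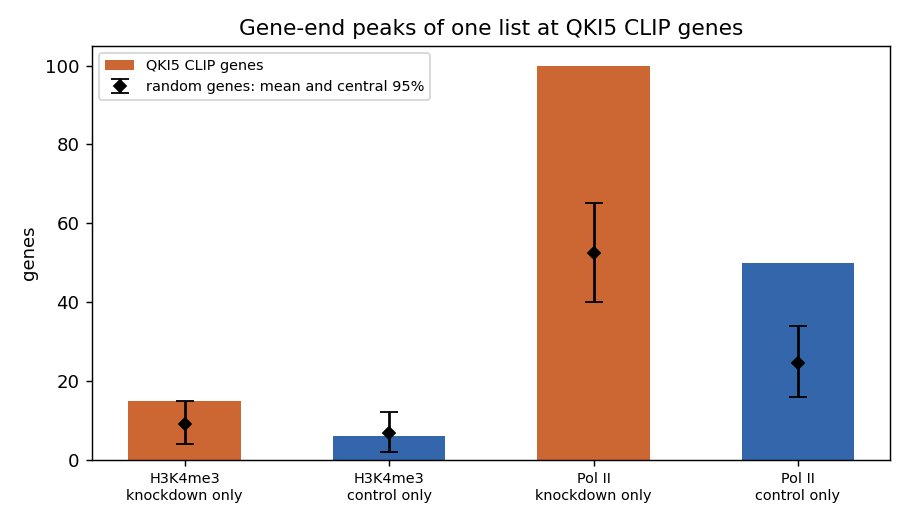
Number of QKI5 CLIP genes with a gene-end peak in knockdown alone (orange) or control alone (blue) for H3K4me3 and Pol II, counted over CLIP genes without a peak in the other list, with the mean and central 95% of 10000 random gene lists matched on gene length (black). For Pol II both bars, 100 and 50, lie above the random range.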

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

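The comparison of small and mitochondrial RNA between the CLIP lists was chosen after its result had been seen, and the test of read depth before.

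CLIP peaks on the mitochondrial chromosome lay outside the comparisons, which covered chromosomes 1 to 22, X and Y. There were 20 in the knockdown list, 2.99% of its peaks (1.84 to 4.58), and 35 in the control list, 0.477% (0.332 to 0.663), so their share was above the control level. The knockdown and control lists held 9 and 4 peaks at MT-RNR2, 3 and 3 at MT-TT, and 1 and 2 at MT-TP.

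Over all contigs the knockdown CLIP list held 669 peaks and the control list 7337. Mitochondrial and small non-coding RNA made up 6.28% (4.56 to 8.39) of the knockdown list and 0.954% (0.744 to 1.20) of the control list, 42 and 70 peaks, but a background of such RNA would add peaks, so this share does not bear on why the list is shorter. On chromosomes 1 to 22, X and Y, 70 of 94 knockdown peaks with 20 reads or more, 74.5% (64.4 to 82.9), had a control peak within 100 bp on the same strand, and 60 of 555 peaks with fewer reads, 10.8%, did. A lower read depth and a loss of QKI5 from its targets cannot be told apart by these values, because strong peaks at abundant RNA would recur in either case, peaks of few reads lie near the calling threshold, and the read totals are unknown. The factors of 15.2 and 30.9 that link reads to enrichment, read as background over QKI5 CLIP totals, differ by 2.03 times, which would leave the knockdown list fewer CLIP reads per background read, but no source states their meaning.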

How the results depend on the processing

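Chosen after seeing the data were leaving out 501 bp peaks, merging adjoining CLIP peaks, using knockdown CLIP genes, the 5 kb rule at CLIP genes, matching on H3K4me3 width and the other settings for the CLIP members of the fixed lists. No paired analysis was possible because each list pools both replicates, which also rules out leaving out a replicate. The depth of the libraries is unknown. All settings of the ACUAAY and intron results were not run for want of a genome and annotation: stronger peaks, small RNA left out, control peaks absent from knockdown, peaks extended on each side, and the opposite strand. Of the main results, 53 setting values stayed within their interval, within 1.5 times or on the same side of the bounds, 36 moved, 7 fell inside the bounds, 2 passed them and 1 reversed. The causes below were not tested, except where a stricter or wider rule by its construction keeps fewer or more items.

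Pairs give control then knockdown. With overlap of at least 50% of each peak, shared peaks were 83.9% and 86.3% (H3K4me3), 43.4% and 41.3% (Pol II) and 1.18% and 13.4% (CLIP). Within 500 bp they were 89.1% and 91.6% (H3K4me3) and 69.2% and 65.1% (Pol II). ChIP peaks above the median of their list by width gave 99.95% and 100% (H3K4me3) and 90.8% and 89.0% (Pol II). Wide peaks overlap more easily, so these are not shares of peaks with strong signal. CLIP peaks above the median of their list by -log10 p gave 3.45% and 33.5%. Of such control CLIP peaks, 14.9% lay on H3K4me3 peaks and 15.5% on Pol II peaks. Lists of the same length gave 89.7% and 90.1% (H3K4me3), 62.4% and 61.5% (Pol II) and 16.9% of control CLIP peaks. Without 501 bp peaks the shares were 94.0% and 95.1% (H3K4me3) and 78.8% and 74.7% (Pol II), and merging adjoining CLIP peaks gave 14.2% of knockdown sites. H3K4me3 genes in a single list numbered 406 and 418 over all biotypes and 44 and 84 with no peak within 5 kb, and Pol II genes 961 and 1653, then 168 and 496.

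The percentile of lost H3K4me3 peaks at CLIP genes moved inside the bounds with stronger CLIP peaks (8.76), lists of the same length (8.565), knockdown CLIP genes (9.88) and the 5 kb rule (8.475). For gained H3K4me3 peaks it reversed with stronger CLIP peaks (30.8) and moved inside with lists of the same length (96.8), knockdown CLIP genes (92.3) and the 5 kb rule (92.06). For lost Pol II peaks it passed the lower bound with knockdown CLIP genes (1.03) and the 5 kb rule (1.42), and stayed inside with H3K4me3 width matched as well (27.9) and with both widths but not gene length matched (58.6). For gained Pol II peaks it was 100 under every setting run. The named ChIP genes were sensitive to the definition of absence: with no peak within 5 kb, the genes kept were 2 of 12 and 1 of 11 for H3K4me3 in control and knockdown alone, and 1 of 15 and 5 of 17 for Pol II.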

Other observations

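The widths of shared gene-end peaks, the tests of peak width in the shared Pol II lists, of H3K4me3 width at CLIP genes and of both directions of Pol II change, the use of knockdown CLIP genes and the 5 kb rule at CLIP genes were chosen after the results had been seen, and the tests of narrow peaks, gene length and control peak width before.

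At genes with a gene-end peak in both lists, the widest H3K4me3 peak was wider in knockdown at 41.9% of 13350 genes, with a median log2 ratio of -0.04, and the widest Pol II peak at 56.8% of 11551 genes, with a median of 0.08. Of myeloid transcription factor genes 13 of 20 had a wider Pol II peak in knockdown, at percentile 87.9. CEBPA, a factor of granulocyte and monocyte development, had 12256 bp in control and 16924 bp in knockdown, while KLF2 had 5645 and 4618 bp, BCL6 2094 and 1557 bp and MITF 1510 and 1056 bp. IRF8 had 8613 and 24799 bp, but its control peak (85897448 to 85906060) and knockdown peak (85905880 to 85930678) lay at mostly different positions. All of these genes were named after their values were seen. None of the 12 fixed lists stood apart by its percentile for either mark. Immediate early genes came nearest for Pol II, with 11 of 17 wider in knockdown at percentile 97.445, and macrophage and monocyte genes for H3K4me3, with 2 of 11 at 3.365. A width can change when neighbouring peaks are joined or split, and the widest peak can lie at either end of a gene, so a width is not a level.

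The Pol II lists shared fewer peaks than the H3K4me3 lists. A larger number of narrow Pol II peaks is argued against as the whole cause. At 501 bp the control lists still differed by 6.11 percentage points, with 31.6% of H3K4me3 and 25.5% of Pol II peaks shared. In the knockdown lists these shares were 42.9% and 21.3%. Narrow peaks as a part of the cause stay open, since 29.1% of control Pol II and 9.67% of control H3K4me3 peaks were 501 bp wide. The size of that part was not measured. Of control Pol II peaks in the upper quartile of width, 97.7% (97.4 to 98.0) had a knockdown peak, but wide peaks overlap more easily and the lists give no signal, so peaks near the calling threshold and a change of weak Pol II sites by the knockdown cannot be told apart. Neither was tested further, because the replicates are pooled.

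CLIP genes had more Pol II peaks in knockdown alone than random genes, which were not matched on expression. So did genes with a knockdown CLIP peak, at 19 of 64 and percentile 100. Whether gene length and peak width account for the number of lost peaks cannot be told, since its percentile was 0.025 without matching, 11.1 with it, 27.9 with H3K4me3 width matched as well and 58.6 with both widths but not gene length, all but the first inside the bounds, yet 1.42 with matching when no peak lay within 5 kb, and the width of the H3K4me3 peak is argued against as the whole cause of the gain, which stayed at percentile 100 with a random mean of 63.6 (51 to 76). Peaks near the calling threshold in both directions stay open, since 66.7% of CLIP genes and 67.6% of other genes with a Pol II peak in a single list had it in knockdown, a difference of -0.940 percentage points (-9.30 to 6.69), and control-only peaks were 2.03 times the random mean. With no peak within 5 kb the control-only count was 18 against 13.1, at percentile 92.3, the gain stayed at 100, and the difference was 5.02 points (-5.30 to 13.2). An effect of QKI5 on Pol II at these genes, which the design names, stays open as an untested hypothesis.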
